A study of Mus musculus with 2 samples.

How the data were processed

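H3K36me3 ChIP-seq peaks from whole intestine of mice at postnatal day 0 were used, with 1 group of 2 biological replicates. Each replicate was a pool of both sexes, from 15 mice for replicate 1 and from a number not given for replicate 2, and each was sequenced as 2 technical replicates on Illumina HiSeq instruments from fragments of 300 to 500 bp, per the labels. A control experiment was named in the labels and its data were not used here.

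The deposited files were 4 peak lists with 10 columns on mm10, per the notes beside the files. The list of each replicate was made from its filtered alignments with further files whose content the notes do not name, 2 of them for replicate 1 and 1 for replicate 2. The pooled list was made from the alignments of both replicates and the replicated list from the 2 replicate lists and the pooled list. The peak caller, the aligner, their versions and the thresholds are not given in the sources used here. Each deposited peak has a score scaled by the caller, which was not analysed. The fold enrichment is the deposited ratio of signal to the caller's own background, and it was compared within lists only. The −log10 p of each peak is the deposited value before adjustment, and it was never below 2. The −log10 q is the deposited p-value after the caller's adjustment within a list, and it was used as an alternative threshold. The deposited offset of the peak summit was not analysed. No counts accompany the lists, so depth per library and the counting error of each value are unknown, and the spread between the 2 replicates is the only measure of precision.

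Peak positions were compared with GENCODE vM21, whose coordinates are on mm10 (GRCm38), and GC content was computed from the matching RefSeq genome sequence. Every peak on chromosomes 1 to 19, X and Y ended within the length of its chromosome in that sequence. Overlapping peaks of a list were merged before lengths were summed, and shares of the genome were taken over the bases with known sequence. Bases were assigned in the order promoter (1 kb on either side of the start of a coding gene), exon, intron and intergenic, so that each base counted in 1 class. Covered share was the percentage of a gene's span, from its first to its last annotated base, that lay in peaks of a replicate's own list. All 21938 protein-coding genes on these chromosomes were considered, and the 717 with spans under 1 kb were left out, which left 21221. Of these, 4641 overlapped the span of another coding gene, and such genes are named as overlapping where they appear. A gene was called marked when at least 10% of its span was covered in each replicate.

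The profile along genes used 10 equal bins over marked genes of at least 10 kb, and exons were compared with introns in the same genes without the first exon. Flanking sequence was taken for 5 kb on either side of those genes that had no other coding gene within that distance. Agreement between replicates was set against 100 random circular shifts of the peaks of replicate 2 along each chromosome.

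In total, 37 gene lists were used. Of these, 27 were written by hand (housekeeping, H3K36 methylation writers, erasers and readers, cell cycle, absorptive enterocyte, epithelial transcription factors and junctions, suckling-period enterocyte, weaning and adult epithelium, goblet, enteroendocrine, stem and progenitor, smooth muscle, fibroblast and mesenchyme, enteric neuron and glia, endothelium, immune, erythroid, mesothelium, pancreas, liver, stomach, skeletal and cardiac muscle, brain, photoreceptor, germ cell, imprinted, proximal and distal intestine). The other 10 were families taken by symbol (ribosomal proteins, respiratory chain, proteasome, splicing factors, Zfp zinc finger genes, clustered protocadherins, Hox, replication-dependent histones, olfactory and vomeronasal receptors). Sct, Hba-a1, Ahsp, Tnp1 and the imprinted noncoding genes H19, Meg3, Kcnq1ot1 and Airn were not measured as coding genes of at least 1 kb under those symbols. Some lists share genes, with 2 in common between enterocyte and suckling genes (Amn and Cubn), 3 between distal intestine and Hox genes, 3 between housekeeping and ribosomal genes and 2 between housekeeping and proteasome genes.

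For each list and replicate the median covered share was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of gene span. A list stood apart when both replicates lay at or above the 97.5th percentile or at or below the 2.5th. The difference between the replicates, replicate 2 minus replicate 1, was placed in the same way. No test across samples was possible with 1 group, and no p-value was computed. The 6 lists called broadly active were housekeeping, cell cycle, ribosomal, respiratory chain, proteasome and splicing genes, with 305 genes in all. The list calls were tested on simulated data with 200 genes raised by a known amount. Lists of 25 genes raised by 20 percentage points were called in 20 of 20 cases, those raised by 10 points in 8 of 20, and unchanged lists in 3 of 500. For the difference between replicates, lists raised by 10 points were called in 20 of 20 cases and unchanged lists in 16 of 500. The simulated coverage was shuffled among genes of similar span, which removes any tie of a list to GC content or to covered genes. The rates for unchanged lists therefore do not include calls that arise from such ties.

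The lists, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 3 members with the highest mean covered share and the 1 with the lowest for each list described, the 10 genes of at least 20 kb with the highest mean, the 5 genes of at least 10 kb marked in a single replicate with the largest difference in each direction, and the 5 replicated peaks with the highest fold and the 5 widest. The other settings fixed in this way were a −log10 q of at least 2, a fold of at least 3, equal numbers of peaks, joining of peaks within 500 bp, an overlap of at least 50% of a peak, promoters of 2 kb, minimum coverage of 5% or 20%, other minimum spans, genes without overlaps, random lists not matched on span, the pooled or replicated list in place of the replicates, and each replicate alone. Chosen after seeing the data were the share of members marked as the statistic of a list, random lists matched on GC content and span (20 bins of GC content, each with 3 bins of span), the replicate difference over genes with a mean coverage of at least 5%, and the comparison of exons with introns beyond the midpoint of each gene. The computations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.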

Results

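Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark laid down over the bodies of genes as they are transcribed, was profiled by chromatin immunoprecipitation and sequencing in whole intestine of newborn mice (postnatal day 0). The series held 1 group of 2 biological replicates, each a pool of intestines of both sexes. Replicate 1 was pooled from 15 mice, and each library combined 2 technical replicates, per the labels. The deposited data were 4 lists of peaks on the mm10 assembly: 1 for each replicate, 1 for both replicates pooled, and 1 of replicated peaks. Peak positions, fold enrichment and −log10 p were the authors' own values, and no read counts accompany them, so the depth of each library is unknown. With a single group no contrast between conditions could be tested, and values below are means ± SD of n = 2 replicates unless stated otherwise.

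The strongest and the widest H3K36me3 peaks lay within protein-coding genes. The replicated peak with the highest fold enrichment, 11.8, covered 13911 bp (chromosome 15, 76170920 to 76184830) at the 3′ end of Plec, which encodes the cytoskeletal linker plectin, and 83.2% of its bases were exonic. The next highest folds were found in Zfp329 (10.6), Zfp157 (10.3), Spred2 (9.93), a negative regulator of Ras signalling, and Shroom3 (9.58), which shapes epithelial cells by apical constriction. The widest replicated peak, 17646 bp (chromosome 12, 110615324 to 110632969), lay in Dync1h1, the heavy chain of cytoplasmic dynein, and crossed 22 exons. Peaks of 16421 bp in Zmiz1, 15466 bp in Ube3b and 14473 bp in Fasn, the fatty acid synthase, came next, and the Plec peak was the fifth widest. Of the bases of the Plec peak, 93.5% were covered in replicate 1 and 98.8% in replicate 2.

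**Figure D1:**
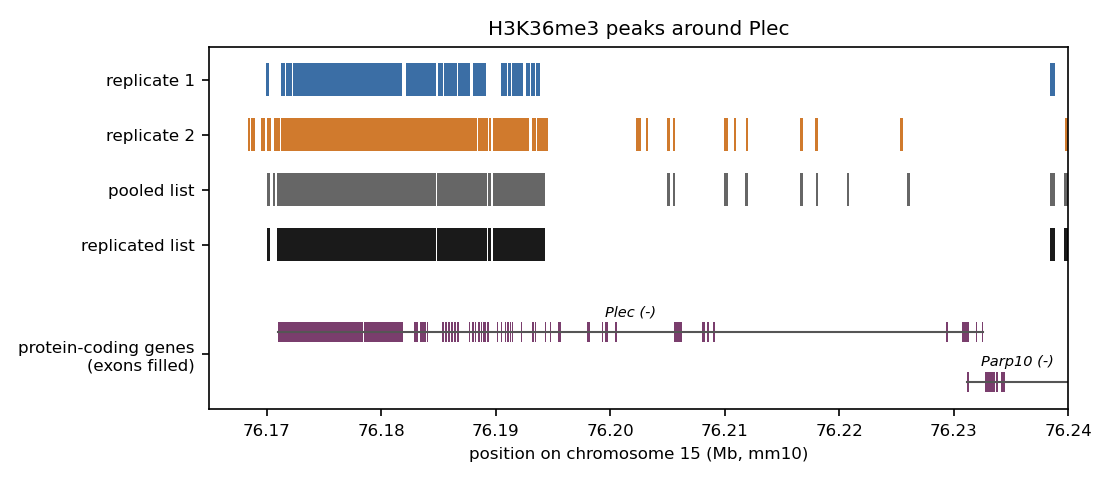
Peaks over Plec on chromosome 15 (mm10; x axis, position in Mb) in the 4 deposited lists, with the exons of the coding genes as filled blocks. Each bar is a peak drawn to scale. The replicated peak of 13911 bp spans the exons at the 3′ end of Plec, where both replicates were covered.

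Replicate 1 held 155853 peaks covering 77.9 Mb, or 2.94% of the known sequence, and replicate 2 held 201550 peaks covering 86.3 Mb (3.26%). The pooled list covered 112 Mb with 202672 peaks, and the replicated list covered 84.8 Mb with 104576 peaks. The 2 replicates shared 43.4 Mb, which was 55.8% of the peak bases of replicate 1 and 50.4% of those of replicate 2. The Jaccard index of their bases was 36%, against 1.76% ± 0.109 (SD of 100 shifts) when the peaks of replicate 2 were shifted along each chromosome. Of the peaks of replicate 1, 69.1% overlapped a peak of replicate 2, against 6.53% ± 0.337 after shifting. The shifts also moved peaks out of genes, so any 2 lists that lie in gene bodies would exceed them. The gap therefore does not measure agreement beyond that shared location. Over 21221 protein-coding genes, the share of a gene's span that was covered by peaks correlated between the replicates with r = 0.907 and rho = 0.914, values taken across genes, which are not independent replicates. Both values include the 8064 genes (38.0%) without a peak in either replicate, so they do not measure agreement among covered genes alone.

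Coding genes held 95.4% ± 1.07 of all peak bases, although their spans make up 39.3% of the known genome. Exons were the most enriched class, with 23.9% ± 0.240 of peak bases, 7.34-fold ± 0.0734 their share of the genome. Introns held 71.1% ± 0.994, a 2.02-fold ± 0.0283 enrichment. Promoters, taken as 1 kb on either side of transcription starts, were depleted to 0.288-fold ± 0.133, and intergenic sequence to 0.0752-fold ± 0.0171. With promoters of 2 kb on either side the promoter value was 0.460-fold.

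H3K36me3 built up along genes towards their 3′ ends. In 5259 marked genes of at least 10 kb, peaks covered 3.83% ± 0.781 of the first of 10 equal bins, 34.7% ± 0.150 of the fifth and 48.2% ± 0.404 of the ninth, and 44.9% ± 1.2 of the last. Coverage of the last bin was 11.9-fold ± 2.12 that of the first. Around 1822 of these genes with no other coding gene within 5 kb, the mark ran on past the annotated end, covering 26.3% ± 1.85 of the first kb downstream, 12.9% ± 2.09 of the second and 3.05% ± 0.568 of the fifth. The first kb upstream of the start was covered to 0.190% ± 0.220. Within the same 5259 genes, exons other than the first were covered to 48.2% ± 0.0655 and introns to 25.7% ± 0.244, a ratio of 1.87 ± 0.0152. Beyond the midpoint of each gene exons were covered to 50.9% ± 0.105 and introns to 35.7% ± 0.521, which gave a ratio of 1.42 ± 0.0237.

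**Figure D2:**
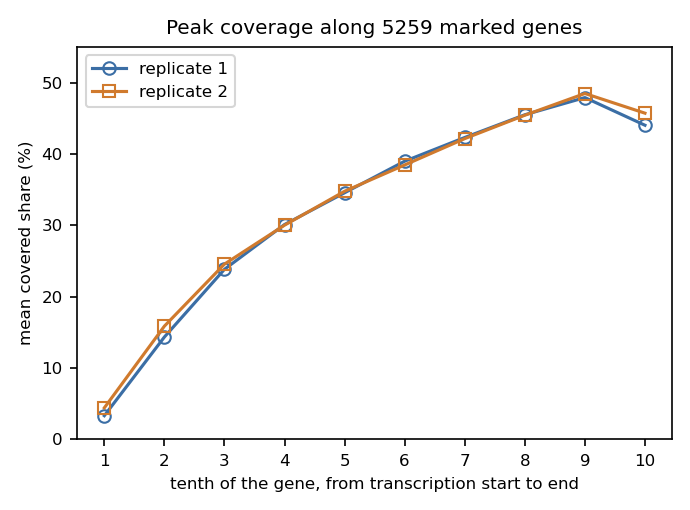
Share of bases covered by H3K36me3 peaks (y axis, percent) in 10 equal bins from the start to the end of transcription (x axis), averaged over 5259 marked genes of at least 10 kb, with a line per replicate. Coverage was lowest in the first bin (mean 3.83%) and highest in the ninth (48.2%) in both replicates.

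In total, 6764 of 21221 coding genes (31.9%) were marked, which required peaks over at least 10% of the gene's span in each replicate. The genes of at least 20 kb with the highest covered share included Ddb1 (79.8% ± 8.53), a DNA damage binding protein whose span overlaps another coding gene, and the spliceosome components Prpf8 (78.6% ± 0.137; chromosome 11, 75486816 to 75509449) and Snrnp200 (76.7% ± 4.06; chromosome 2, 127208386 to 127240451). Sec24c (75.8% ± 0.131) of the COPII vesicle coat, the histone methyltransferase Kmt2d (75.4% ± 7.29), the ubiquitin ligases Ubr4 (75.4% ± 0.0910) and Ube3b (75.1% ± 8.81), Gtf3c1 (75.1% ± 0.909), Tln1 (75.1% ± 0.882) and the histone demethylase Kdm4a (74.6% ± 4.70) completed the 10 highest. Ubr4 and Tln1 also overlap other coding genes. Neither replicate had a peak in 8064 genes (38.0%). A gene minimum of 20% coverage in place of 10% lowered the number of marked genes to 4434.

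Housekeeping genes and gene families of the basic cell machinery carried the mark far more often than genes of equal length drawn at random. The families were taken by symbol, so a member need not be active in every cell. Of 30 housekeeping genes 25 were marked, against 9.88 expected from random lists matched on span, with Eef2, a translation elongation factor (72.6% ± 8.03), Actb (66.8% ± 0.0970) and Hsp90ab1 (63.0% ± 9.17) at the top and Ubb (1.37% ± 1.94) at the bottom. Splicing factors were marked in 35 of 43 cases (14.8 expected), led by Sf3b3 (73.6% ± 12.5), whose span overlaps another coding gene, Hnrnpul1 (72.3% ± 4.21) and Sf3a1 (66.7% ± 1.67), while Sf3b5 was not covered. Proteasome subunits were marked in 30 of 39 cases (13.3 expected), among them Psmd3 (61.2% ± 4.13), Psmc1 (59.8% ± 6.61) and Psmd7 (59.6% ± 1.78), with no coverage of Psma8. For ribosomal proteins the count was 61 of 83 (15.0 expected), with Rps3 (66.7% ± 5.98), Rps19 (64.3% ± 2.75) and Rps5 (57.7% ± 0.322) highest and Rpl3l uncovered. Subunits of the mitochondrial respiratory chain were marked in 62 of 89 cases (24.0 expected), including Ndufa10 (69.2% ± 3.57), Uqcrc1 (67.9% ± 0.708) and Atp5b (66.5% ± 1.64). Cox7b2 of that list was not covered.

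Cell cycle genes and the genes of the H3K36 methylation pathway itself were also marked in most cases. Of 26 cell cycle genes 23 were marked (10.3 expected), with the replicative helicase subunits Mcm6 (49.2% ± 7.56) and Mcm4 (47.6% ± 9.01) and the mitotic cyclin Ccnb2 (48.7% ± 12.8) highest and Rrm2 (8.17% ± 1.4) lowest. Of 24 writers, erasers and readers of H3K36 methylation 20 were marked (8.73 expected). They included Kdm4a (74.6% ± 4.70), Supt6 (62.4% ± 3.80), whose span overlaps another coding gene, Brpf1 (55.6% ± 2.04) and Setd2 (33.0% ± 9.37), the enzyme that places the trimethyl mark, and the lowest was Dnmt3b (5.37% ± 0.318). Zfp zinc finger genes, grouped by symbol, were marked in 187 of 365 cases (139 expected), with Zfp869 (82.7% ± 14.1), Zfp335 (76.3% ± 0.953, overlapping another coding gene) and Zfp110 (70.2% ± 7.95) highest and Zfp808 uncovered. The median covered share of each of these 8 lists stood above the upper percentile bound of 10000 random lists matched on span in both replicates. Each of these lists also stood above random lists in the 11 other settings, which include the share of members marked as the statistic and the use of a single list of peaks. The percentiles describe these libraries and are not a test across animals.

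**Figure D3:**
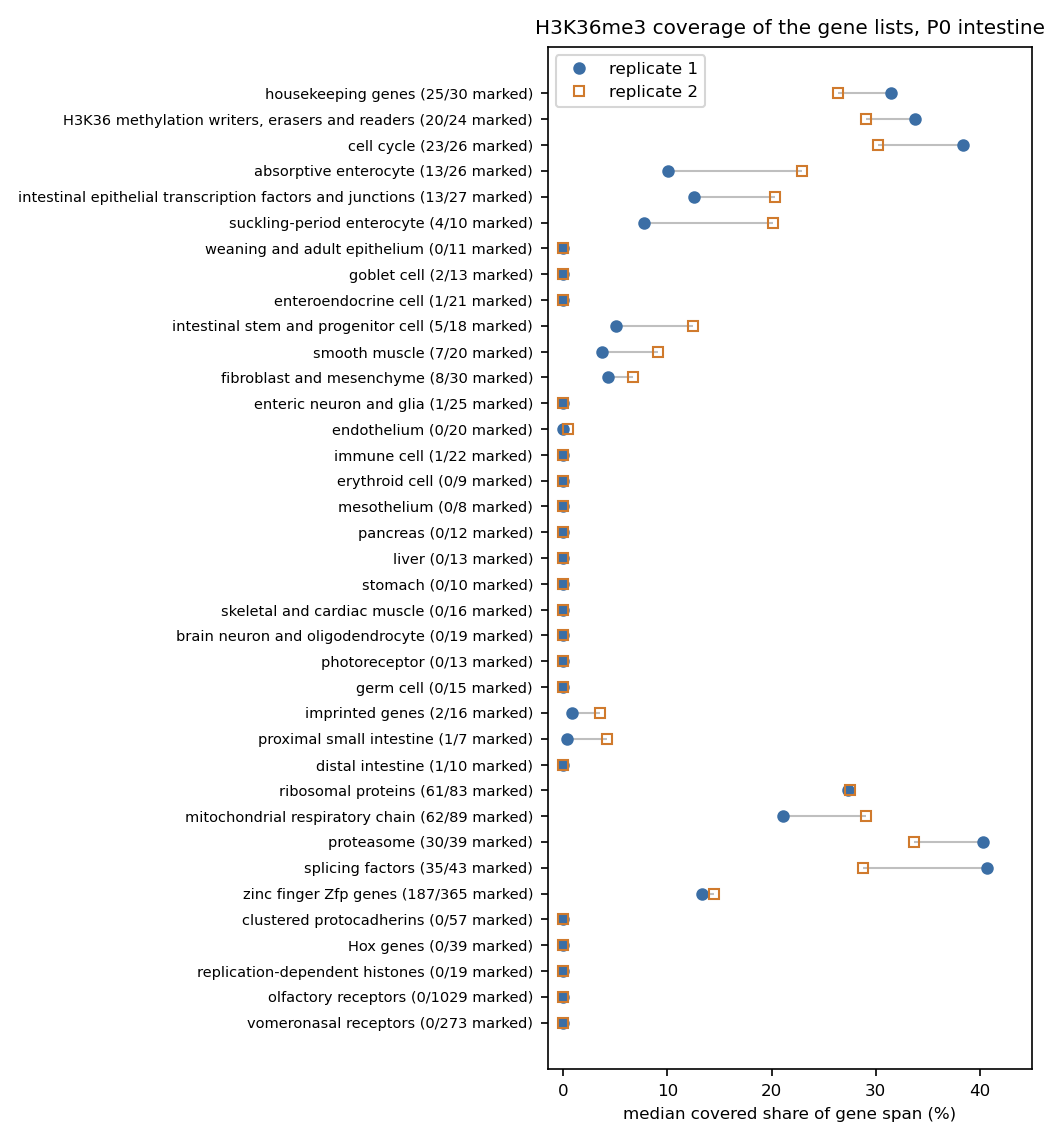
Median share of gene span covered by H3K36me3 peaks (x axis, percent) for each gene list (y axis), with a filled point for replicate 1 and an open one for replicate 2. Lists of broadly active genes, such as splicing factors (35 of 43 marked), lie at the right, and the lists of other organs lie at 0 in both replicates.

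Marked genes of the epithelium included general epithelial genes and genes of its absorptive cells. Of 27 epithelial transcription factors and junction genes 13 were marked (9.03 expected), led by the adhesion molecule Epcam (34.9% ± 7.03), the brush border linker Ezr (31.5% ± 5.33, overlapping another coding gene) and the transcription factor Elf3 (30.0% ± 8.38), with Hnf4g (1.49% ± 0.528) lowest. This list stood above its random lists in both replicates (97.9th and 99.4th percentiles). The call was lost in 5 of 11 settings, among them random lists matched on GC content as well as span (94.3rd and 94.0th percentiles).

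Absorptive enterocyte genes were marked in 13 of 26 cases (8.97 expected). Vil1, the actin bundler of microvilli (48.6% ± 16.1, overlapping another coding gene), Apob, the structural protein of chylomicrons (42.0% ± 0.364), and the brush border motor Myo1a (40.9% ± 36.3) were covered most. The fatty acid binding protein gene Fabp2 was covered in neither replicate, although the pooled list covered 15.8% of its span. Myo1a differed widely, with 15.2% in replicate 1 and 66.6% in replicate 2. The list's median lay at the 93.7th percentile in replicate 1 and the 99.7th in replicate 2, so it did not stand apart in both. Of 10 genes of the suckling enterocyte 4 were marked (2.81 expected), with Glb1 (45.5% ± 8.55, overlapping another coding gene), Ass1 (44.7% ± 18.9) and Amn (35.3% ± 25.3) highest and Lrp2 (0.178% ± 0.252) lowest, and its percentiles were 88.1 and 99.5. Both lists stood apart on replicate 2 alone and on the pooled list, and enterocyte genes also on the replicated list. On replicate 2 alone, where a gene need pass in a single list, 20 enterocyte genes and 21 epithelial transcription factors and junction genes were marked, against 13 and 15 on replicate 1 alone. With a −log10 q of at least 2 the number of marked enterocyte genes was 8, and with a coverage minimum of 20% it was 5, as for epithelial transcription factors and junction genes. By the share of members marked, none of the enterocyte (95.2nd percentile), suckling (79.6th) and epithelial transcription factor and junction lists (94.8th) stood apart. None of 11 genes of the weaned or adult epithelium was marked (3.71 expected). The adult sucrase gene Sis was uncovered and the highest of that list was Arg2 (9.27% ± 0.903, overlapping another coding gene).

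Other epithelial lineages and the layers of the gut wall held about as many marked genes as random lists of equal length, or fewer. Goblet cell genes were marked in 2 of 13 cases (4.61 expected), Xbp1 (58.1% ± 3.62), a factor of the secretory pathway, and Muc13 (44.3% ± 4.08). In the enteroendocrine list Ghrl, which encodes ghrelin, was the marked gene (50.5% ± 6.00; 1 of 21, 6.27 expected). Stem and progenitor genes were marked in 5 of 18 cases (5.27 expected), with the Wnt target Axin2 (33.8% ± 13.9), Ccnd1 (27.1% ± 5.32, overlapping another coding gene) and Ephb3 (23.6% ± 16.6) highest and Olfm4 uncovered. Smooth muscle genes were marked in 7 of 20 cases (6.83 expected), led by Smtn (46.1% ± 7.33), Tpm1 (44.4% ± 3.25) and Srf (40.8% ± 18.4), and fibroblast and mesenchyme genes in 8 of 30 (9.43 expected), led by the Hedgehog receptor gene Ptch1 (39.9% ± 3.89), Col6a1 (30.9% ± 15.2) and Sparc (25.4% ± 9.01). Enteric neuron and glia genes were marked in 1 of 25 cases (7.66 expected), the neuregulin receptor gene Erbb3 (39.4% ± 12.8), and immune cell genes in 1 of 22 (6.73 expected), Fcer1g (17.6% ± 3.95). Endothelial genes (0 of 20, 6.46 expected), erythroid genes (0 of 9, 3.37 expected) and mesothelial genes (0 of 8, 2.73 expected) held none, the highest endothelial gene being Eng (13.0% ± 10.6, overlapping another coding gene). On replicate 2 alone the marked genes numbered 10 for the stem cell list, 13 for fibroblasts, 3 for enteric neurons and glia, 3 for immune cells and 2 for endothelium, against 5, 8, 1, 1 and 0 on replicate 1 alone. With a −log10 q of at least 2 the numbers were 3 for stem cells, 4 for smooth muscle and 4 for fibroblasts. Regional markers were few, with Slc40a1, the iron exporter ferroportin (26.3% ± 4.99), marked among 7 proximal genes and the bile acid transporter subunit gene Slc51a (19.4% ± 2.01, overlapping another coding gene) among 10 distal genes, and on replicate 2 alone 3 proximal and 2 distal genes were marked.

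Lists typical of other organs, and several large gene families, held no marked gene. Not 1 of 98 genes typical of pancreas, liver, stomach, skeletal and cardiac muscle, brain, photoreceptors or germ cells was marked, where 31.4 were expected, and the highest was the liver transthyretin gene Ttr (7.13% ± 6.20). No marked gene was found among 1029 olfactory receptors (264 expected), 273 vomeronasal receptors (98.5 expected), 57 clustered protocadherins (12.4 expected), 39 Hox genes (8.98 expected) or 19 replication-dependent histone genes (2.66 expected). Histone genes with spans under 1 kb were not measured, so the 19 are the longer annotated members and do not stand for the family. Replicate 1 sets some of these zeros, since on replicate 2 alone 3 protocadherins, 2 Hox genes and 1 liver gene were marked. All 57 protocadherins overlap another coding gene. The 3 marked on replicate 2 alone, Pcdhgc3, Pcdhgc4 and Pcdhgc5, overlap one another and end at the same base. The protocadherin counts therefore do not stand for separate regions. Imprinted genes were marked in 2 of 16 cases (5.10 expected), and Igf2r (33.5% ± 5.99) was the highest, while 4 were marked on replicate 2 alone and 7 in the pooled list. By the share of members marked, 19 lists stood below random lists. By the median no list did so in both replicates, and 20 of the 37 lists had a median of 0 in both. Coverage cannot fall below 0, so a list with a median of 0 could not stand below where many random lists also had 0. Olfactory receptors, for example, lay at the 50th percentile in both replicates. The lack of low lists by the median is therefore uninformative for such lists. Vomeronasal receptors and protocadherins (1.04th percentile) stood below random lists on replicate 2 alone, and vomeronasal receptors also on the pooled list.

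The 2 replicates differed by gene group. Enterocyte genes were covered more in replicate 2, with a median difference of 6.89 percentage points (23 of 26 genes higher), as were epithelial transcription factors and junction genes (9.20 points, 23 of 27 higher) and genes of the suckling enterocyte (8.29 points). Stem cell (3.98), smooth muscle (4.05), fibroblast (2.68) and respiratory chain genes (1.00) also stood above random lists matched on span. Cell cycle genes were covered less in replicate 2 (−8.34 points), as were splicing factors (−7.68) and proteasome subunits (−2.53). Housekeeping genes (−0.163) and the H3K36 methylation genes (−1.52) stood below random lists by small amounts, and their sign turned in 3 and 2 of the other settings. With equal numbers of peaks the medians shifted to 4.07 points for enterocyte, 2.84 for suckling, 1.62 for stem cell, 1.54 for smooth muscle and 0.322 for fibroblast genes, all still above random lists, to −15.1 for cell cycle genes, and to 0 for the respiratory chain, which then no longer stood apart. This setting removes peaks from replicate 2 alone, so the downward direction of these shifts was fixed in advance. Of genes of at least 10 kb marked in replicate 2 alone, Sema3b (0% and 30.2%), Meltf (4.87% and 35.7%), Gmip (8.01% and 37.0%), Pkp3 (6.21% and 34.0%) and Cdh24 (5.04% and 32.9%, overlapping another coding gene) differed most. Among those marked in replicate 1 alone, Ccne2 (34.1% and 6.17%), Cnot7 (34.6% and 9.68%), Htatsf1 (30.3% and 6.52%), Cip2a (29.3% and 6.42%) and Gtf2a2 (19.7% and 0%) did, and Ccne2 and Cnot7 overlap other coding genes.

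The difference followed GC content over 9334 genes with a mean coverage of at least 5% (rho = 0.743 across genes). In the 10% of genes with the lowest GC content (median 39.0%), the median difference was −7.91 points, and in the 10% with the highest (55.8%) it was 15.4 points. Random lists over all genes had medians near 0 because many genes were uncovered, and limiting the comparison to these 9334 genes changed several calls. Matched on span alone, enterocyte (12.1 points, 20 of 21 genes higher), suckling (16.6 points over 8 genes), epithelial transcription factor and junction (9.95) and stem cell genes (7.89) still stood above, whereas smooth muscle (86.3rd percentile), fibroblast (75.5th), housekeeping (8.04th) and H3K36 methylation genes (9.43rd) did not stand apart. Cell cycle genes (−8.34), splicing factors (−9.35) and proteasome subunits (−2.69) still stood below. Zfp genes (−0.159, against 3.45 in random lists), ribosomal proteins (2.10, against 10.6) and the respiratory chain (2.62, against 6.68) also stood below here. The respiratory chain had stood above over all genes, and ribosomal proteins, which had not stood apart over all genes, stood above (100th percentile) with a −log10 q of at least 2 and without overlapping genes, so neither list had a stable direction. With GC content matched as well, enterocyte genes (2.27 points in random lists) and suckling genes (4.79) stood above, and cell cycle, splicing, proteasome and ribosomal genes stood below. Epithelial transcription factor and junction genes (97.4th percentile), stem cell genes (55th), the respiratory chain (87.8th) and Zfp genes (88.3rd) then no longer stood apart.

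**Figure D4:**
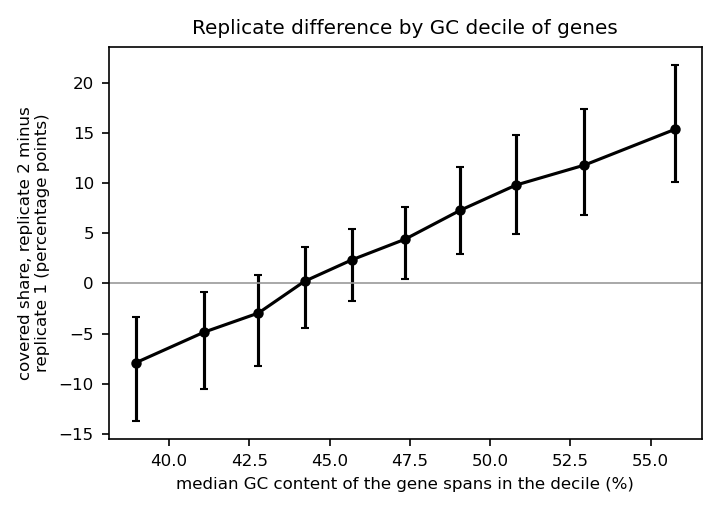
Median difference in covered share between the replicates, replicate 2 minus replicate 1 (y axis, percentage points), against median GC content (x axis, percent) for 10 groups of genes of equal number. Bars span the middle 50% of the genes of each group, and the medians run from −7.91 points at 39.0% GC content to 15.4 points at 55.8%.

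The X chromosome carried few marked genes. On the autosomes 6735 of 20181 genes were marked (33.4%), from 25.6% on chromosome 14 to 39.8% on chromosome 8, against 29 of 877 on the X chromosome (3.31%) and 0 of 163 on the Y chromosome. Peaks covered 0.951% ± 0.140 of coding gene spans on the X chromosome and 7.93% ± 0.497 on autosomes, a ratio of 0.120 ± 0.0101. In the replicated list the ratio was 0.0717. The most covered X genes were the histone demethylase gene Kdm5c (38.4% ± 13.5; 152233020 to 152274535), Hcfc1 (35.6% ± 8.10), the RNA helicase gene Ddx3x (34.5% ± 19) and the translation initiation factor gene Eif2s3x (28.4% ± 15.6), which were named after their values were seen. Of the members of the 6 lists of broadly active genes, 1 of 11 on the X chromosome was marked (Rps4x, 15.0% ± 1.16), against 230 of 294 on autosomes (78.2%).

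**Figure D5:**
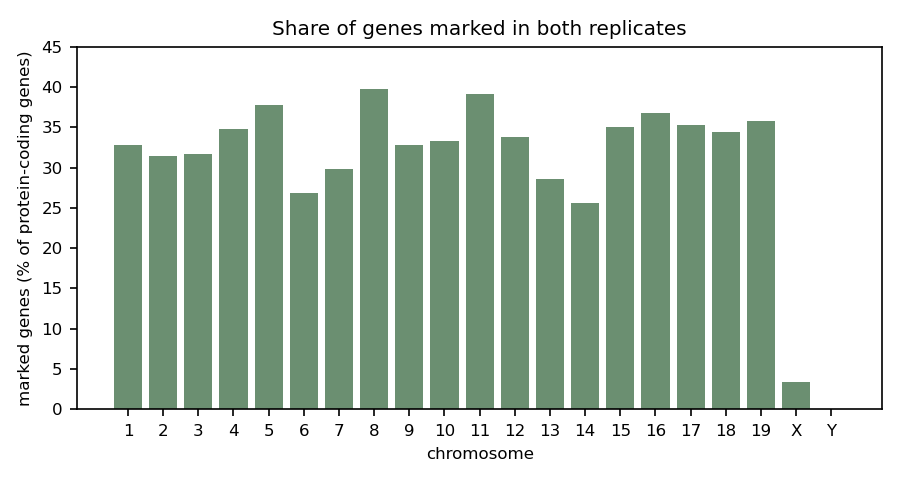
Share of protein-coding genes marked in both replicates (y axis, percent) on each chromosome (x axis), with 1 bar per chromosome. The X chromosome lies at 3.31%, and the autosomes between 25.6% and 39.8%.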

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

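These results come from data that the comparisons of the report do not use, and the test of the noncoding genes was chosen before its result was seen. Outside the spans of coding genes, 60 of 9780 genes annotated as noncoding (0.613%) were marked in both replicates, a signal in genes that no comparison of the report covers. Of the 60, 23 were annotated as long intergenic noncoding RNAs. The rest include pseudogenes such as Mx2 and processed transcripts such as Tmem134 and Anxa13, so the class is wider than RNA genes. The highest of the 60 was 1700056N10Rik (64.9% ± 17.4 of its span, SD, n = 2). Others, chosen after their values were seen, were the small nucleolar RNA host genes Snhg17 (54.0% ± 0.799) and Snhg1 (44.9% ± 1.88), and Malat1 (43.3% ± 14.2), an abundant nuclear RNA. The mark may continue from a neighbouring coding gene, since 53.3% of the marked noncoding genes (32 of 60) lay within 10 kb of a marked coding gene, against 7.83% of unmarked ones. This leaves the other marked noncoding genes open, among them any transcribed on their own, and no biological explanation was tested.

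Outside the gene spans that the report compares, 29 peaks of the replicated list (0.0277% of 104572) lay more than 10 kb from any annotated gene. On scaffolds not placed on a chromosome, which the report leaves out, 4 replicated peaks were found. On the Y chromosome, where no gene was marked, 4 replicated peaks were found between 90737622 and 90742315, and these are among the 29.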

How the results depend on the processing

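Among the other settings, those by share of members marked, by matching on GC content, over genes covered by at least 5% and beyond the midpoint of genes were chosen after the data were seen. With a −log10 q of at least 2 the covered length was 64.8 Mb in replicate 1 and 77.3 Mb in replicate 2, the Jaccard index 34.9%, the share of peaks overlapped 70.3% and 51.0%, the exon enrichment 7.69-fold, the last bin over the first 14.1-fold, exons over introns 1.86, lists below in the replicate difference 3, and the X ratio 0.101. With a fold of at least 3 the lengths were 61.5 and 74.4 Mb, the Jaccard index 34.1%, the overlapped shares 69.3% and 49.4%, and the exon enrichment 7.75-fold. With equal numbers of peaks the Jaccard index was 36.1% and the overlapped shares 62.1% and 61.8%, and with an overlap of at least 50% of the peak the shares were 52.0% and 43.2%. Joining peaks within 500 bp gave 94.6 and 107 Mb and a Jaccard index of 44.2%. The replicated list gave 7.83-fold for exons, 16.7-fold for the last bin, 2.02 for exons over introns and 0.0717 for the X ratio, and the pooled list gave 7.10-fold, 1.98 for exons over introns and 1 list below. Promoters of 2 kb gave 7.61-fold for exons and 0.460-fold for promoters. Genes of at least 20 kb gave 9.16-fold for the last bin and 1.90 for exons over introns, which were 1.42 beyond the midpoint. A coverage minimum of 20% gave 4434 marked genes, fewer by construction. By the share of members marked 19 lists stood below. In the replicate difference, 4 lists stood above over genes covered by at least 5%, and 2 when GC content was matched too. The sign of the replicate difference turned for housekeeping genes, to 0.448 with the q minimum and to 1.08 over genes covered by at least 5% under both matchings, and for H3K36 methylation genes, to 0.203 with the q minimum and 0.781 without overlapping genes. Except where the construction shows it, the cause was not tested. With 1 replicate alone the values ran from 7096 to 8186 marked genes, 94.6 to 96.2% in gene spans, 7.29 to 7.39-fold for exons, 0.194 to 0.382-fold for promoters, 10.3 to 13.3-fold for the last bin, 1.88 to 2.02 for exons over introns, 9 to 11 lists above, 0 to 2 lists below and 0.112 to 0.127 for the X ratio. Of the other values, 988 values of named genes, each under 1 alternative, moved by less than the spread between replicates and 146 by more. Of the marked counts of lists 237 stayed within 1.5 times and 59 did not, and of the list differences 77 moved without a change of sign and 68 took the same value. No paired analysis was possible because the series holds 1 group. Depth is unknown, so genes without a peak cannot be called free of the mark.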

Other observations

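The tests of GC content in the replicate difference, of the share of epithelium and of broadly active X genes were chosen only after the result was seen. The test of GC content and span of X genes was set before. Imprinted genes and noncoding RNAs of imprinted regions showed no common level. Igf2r was covered to 33.5% ± 5.99 (SD, n = 2), while Nnat reached 8.79% in replicate 1 and 52.7% in replicate 2 and was not marked, Gnas was covered to 10.5% ± 0.629, and Ndn was uncovered. Nnat and Gnas overlap other coding genes. Among the noncoding RNAs, H19 was uncovered, and Meg3 (9.23% ± 9.35), Airn (7.13% ± 3.70) and Kcnq1ot1 (3.97% ± 1.02) were covered in part. Neat1, the scaffold RNA of paraspeckles, was covered to 11.6% ± 5.76. Among the broadly active genes, those of 1 to 2 kb were marked in 2 of 17 cases (11.8%), against 69 of 94 (73.4%) at 2 to 5 kb, 107 of 131 (81.7%) at 5 to 20 kb, 48 of 52 (92.3%) at 20 to 50 kb and 5 of 11 (45.5%) over 50 kb. Those over 50 kb include Psma8 and Cox7b2, which were uncovered and belong to families taken by symbol. On the X chromosome, Kdm5c, Ddx3x and Eif2s3x, known to escape X inactivation, ranked 1, 3 and 4 by covered share, and Kdm6a, which also escapes it, ranked 98 (5.28% ± 4.30). These genes were chosen after their values were seen.

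All 104576 replicated peaks were present in the pooled list with the same values. Of them, 86039 met an overlap of 50% with a peak of each replicate. The overlap was counted when it held at least 50% of either the replicated peak or the replicate's own peak. The other 18537 (17.7%) did not meet it, and 412 overlapped no peak of either replicate.

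Coverage differed between the replicates by gene group, and a GC-dependent difference between the libraries or their peak calls may account for part of this. The difference followed GC content with rho = 0.586 across 271 genes of the 6 broadly active lists. Those lists include cell cycle genes, and whether a difference in cell types acts less on them was not tested. With GC content and span matched, over genes covered by at least 5%, cell cycle, splicing, ribosomal and proteasome genes still stood below random lists. Their percentiles were 0.01, 0.0, 0.7 and 2.4, so these lists differed beyond what GC content and span account for. Housekeeping and respiratory chain genes did not stand apart in that comparison. GC content as the whole source of the enterocyte difference is argued against by the 100th percentile of its 21 genes covered by at least 5% (median 12.1 points) among random lists matched on GC content and span. Over all 26 enterocyte genes, without matching on GC content, the median fell from 6.89 to 4.07 points with equal numbers of peaks. That setting removes peaks from replicate 2 alone, so the difference could only fall. The fall therefore does not bear on the source of the enterocyte difference. A larger share of epithelium in the second pool remains open, because smooth muscle and fibroblast genes, which it would lower, lay at the 29.8th and 6.21st percentiles of matched lists and neither bound set for the test was met. Both pools were of postnatal day 0 per the labels. The handling and section of gut in each pool could not be separated from the libraries. Nor could the further files used to make the replicate lists, 2 for replicate 1 and 1 for replicate 2. No biological difference was tested, since the design gives no groups.

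Few genes of the X chromosome were marked, 29 of 877. A lack of broadly active genes there is argued against by the members of the 6 broadly active lists, of which 9.09% on the X chromosome were marked against 78.2% on autosomes, where the lowest of the random autosomal sets of 11 held 3 marked genes. GC content and span are argued against by matched autosomal sets, of which the lowest of 10000 held 198 marked genes. A weaker signal near the threshold of the peak calls was tested by the ratio of X to autosomes. That ratio was 1.18 ± 0.206 times as high in the pooled list as among peaks with a fold of at least 3. The bound set beforehand against this explanation was met by the mean and by replicate 2 (1.03) but not by replicate 1 (1.32). The bound set for it was met in neither replicate. Because the replicates disagree, a weaker signal may contribute and cannot be told apart. Of the broadly active X genes, Pgk1 and Psmd10 reached the 10% minimum in replicate 2 only, while others such as Rpl39 and Rpl10 were uncovered. The mix of sexes in each pool, and with it the number of X copies, stays open as untested.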
